A study of Mus musculus with 27 samples.

How the data were processed

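Ovaries of young and aged mice were profiled by 3' tag sequencing of polyA RNA, with RNA taken by RNeasy mini kit and DNase I digestion and libraries made with a Lexogen QuantSeq kit, per the labels' protocols. The values are whole-number counts per gene as deposited, in 1 table with 27 columns that match the labels' short names and 0 columns of other samples, not scaled between libraries. The submitters' processing notes name RSEM 1.2.3, DESeq2 and the mm10 build, with no role for any of them. The gene annotation, any filter and the strand of counting are not stated in the sources used here, so reads of overlapping or antisense genes may count for either. Of the 51789 gene IDs, 51596 received a symbol and coordinates from GENCODE M21 (GRCm38), whose symbols are used throughout, and Ensembl IDs are as in the table. The labels name a mouse and a replicate number for each library, and replicates are taken as separate mice. Within groups no library was a copy of another, and pairs between groups were not compared. Over the 48 pairs within groups, the chi-square per gene ran from 20.5 to 208, and counts of mitochondrial genes were 0.

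Groups came from the labels: young untreated, aged untreated and aged treated in each experiment, the treatment being TRi-1 in experiment 1 and auranofin in experiment 2, per the labels. Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM normalization, filterByExpr on the groups, quasi-likelihood F tests with 1 mean per group and Benjamini-Hochberg adjusted p, with 0.05 as the threshold. The 3 groups of an experiment shared a fit (13 and 14 libraries). The age effect over both experiments and the differences of effects came from 1 fit of all 27 libraries with 6 group means. Adjusted p in the text are edgeR's unless another tool is named. Standard errors are the log2 fold change divided by the square root of F. CPM use TMM library sizes, and log2 CPM a prior count of 2. Folds against a group with no count use a floor of 3 counts over the group, and ratios against 1 to 3 counts carry a 95% counting interval. Such intervals and floors cover counting error only. The same tests were checked on simulated counts drawn from the libraries' means, with 200 genes changed by known folds. Of 4-fold changes, 63.6% were recovered for age in experiment 1, 53.0% for age in experiment 2, 69.7% for TRi-1, 34.9% for auranofin, 72.7% for age over both and 30.3% for each difference test. Of 2-fold changes the shares were 11.9%, 5.97%, 2.99%, 1.49%, 34.3% and 0%, and of 1.5-fold changes 0%, 0%, 1.49%, 0%, 7.46% and 0%. With only 200 genes changed the adjusted threshold is strict. In the age data 34.9% and 10.5% of genes were called in experiments 1 and 2, so these shares are likely too low for age.

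The comparisons, the 34 gene lists and the rule for named genes were chosen before the data were examined. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, at least 5 members) on log2 CPM with p adjusted over the lists of a comparison, and again with an estimated correlation. Members were also counted at an edgeR p adjusted over all genes and adjusted over the list alone. The rule names, for each comparison within an experiment, the 8 largest rises and 8 largest falls by the fitted log2 fold change, which a low count can shift against the ratio, among called genes with a mean of at least 5 CPM and no overlap between groups, leaving unnamed those with only a provisional symbol. It adds the 4 members with the smallest p of each list that passed camera or had at least 3 called members, 10 fixed genes (Txnrd1, Cdkn1a, Cdkn2a, Il6, Il1b, Ccl2, Cxcl10, Isg15, Nqo1, Srxn1) and, where fewer than 10 genes passed, the 6 smallest p. Difference tests name up to 5 genes per direction. Part of the list members so named is printed. Hmox1 under TRi-1, the gene values for age over both experiments and Hoxa11 fall outside the rule and were chosen after their values were seen.

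Many lists share members or hold genes that the ovary itself expresses, such as steroid and stromal genes, and several markers of macrophages and neutrophils are also made by other cells. Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom with quality weights, no filter or at least 5 CPM, only the groups compared or all 27 libraries in 1 fit, replicate number as a block, and each library left out in turn. For lists they were an estimated correlation and the fry rotation test, and for age genes the 200 with the smallest p. Genes called with age in 1 experiment were tested as sets, by camera, in the treatment comparison of the other. Those added after seeing the data left out haemoglobin genes, corrected for GC content of the last 1000 nucleotides and transcript length, left out libraries that stood apart, or left out each library in the list tests. Other groupings of the libraries were drawn with a limit of 100 and seed 1. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. All 27 libraries were kept in the reported results.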

Results

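Gene counts were available for 27 libraries of mouse ovary RNA, 1 library per mouse, from 2 experiments. Experiment 1 held 5 young untreated mice, 4 aged untreated mice and 4 aged mice given TRi-1, an inhibitor of the selenoprotein thioredoxin reductase 1 (Txnrd1). Experiment 2 held 5 young untreated mice, 5 aged untreated mice and 4 aged mice given auranofin, a gold-containing drug that inhibits thioredoxin reductases. The labels give no ages, doses or times of treatment. Library totals ran from 6460903 to 14814381 counts: 6460903 to 10077161 in young, 9791693 to 14814381 in aged and 9183605 to 10784379 in TRi-1 ovaries of experiment 1. In experiment 2 they were 6782228 to 9799253 in young, 10139429 to 14027986 in aged and 9895231 to 14479170 in auranofin ovaries. Levels are CPM (counts scaled by normalised library size, mean ± SD), and changes are log2 fold changes ± standard error.

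The first comparison asks how the ovary differs between aged and young mice. In experiment 1 the 4 aged ovaries held far more transcripts of immune cells and fewer transcripts of oocytes and follicle cells than the 5 young ovaries. Igkc, the constant region of the immunoglobulin kappa light chain, stood at 8507 ± 1263 against 52.1 ± 17.7 CPM (aged against young), a change of 7.35 ± 0.41 (ENSMUSG00000076609, chromosome 6, 70726435 to 70726966). Gpnmb, a glycoprotein of lipid-laden macrophages, stood at 1538 ± 1008 against 9.98 ± 6.68 CPM, a change of 7.29 ± 0.64 (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929). The inflammatory cytokine Il1b stood at 40.8 ± 31.6 against 0.414 ± 0.501 CPM, a change of 6.44 ± 0.69 (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139). H1foo, the oocyte linker histone, stood at 0.0779 ± 0.156 against 48.4 ± 8.76 CPM, a change of -8.90 ± 0.82, and Dppa3, a maternal-effect gene, changed by -4.88 ± 0.49. These 5 genes had edgeR adjusted p of at most 8.7e-06.

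Of the 8 largest rises named by the rule, Glycam1, a mucin-like ligand of L-selectin, was at least 1300.6-fold higher, with 101 ± 66.1 CPM in aged and 0 counts in young ovaries. The others were the immunoglobulin genes Ighg3 10 ± 2.04, Ighg2c 9.80 ± 1.28, Ighg1 8.67 ± 1.26, Igkc and Ighm 6.996 ± 0.57, the ubiquitin-like modifier Ubd 7.35 ± 1.08, and Gpnmb. Counts can be shared between near-identical immunoglobulin genes. Among the largest falls, 7 genes had no count in aged ovaries: Dynlt1b was at least 525.5-fold lower, Fbxw27 at least 302.3-fold, Accsl at least 261.1-fold, Khdc1b at least 202.4-fold, Fbxw14 at least 200.2-fold, Zar1 at least 196.8-fold and Fbxw20 at least 193.9-fold lower. Fbxw18, eighth by the fitted change, was lower by a ratio of 771 (95% counting interval 213 to 6366). Dynlt1b and the Fbxw genes have near-identical relatives, so which copy was counted is uncertain. Without aged replicate 1 the change of Ighg3 was 6.47 and that of Ighg1 7.55. Without young replicate 5 those of Ighg3 and Ighm were 10.89 and 7.74. Il1b changed by 7.36 without young replicate 1 and by 5.71 without aged replicate 3. All 4 aged counts of H1foo came from aged replicate 4, so without it this group held 0.

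Immune cell markers rose as groups. Of the T cell markers, 21 of the 24 tested members rose, 0 fell and 3 did not pass (21 and 0 adjusted over the list alone). Members included Cd3d 3.39 ± 0.35, Cd8a 4.83 ± 0.50 and Trac 4.61 ± 0.48 (camera adjusted p = 9.5e-12, and adjusted p = 0.089 with an estimated correlation). For B cell and plasma cell markers, 22 of the 26 tested members rose, 1 fell and 3 did not pass (22 and 1 adjusted over the list alone). Members included Jchain 5.52 ± 0.36 and Mzb1 6.81 ± 0.50 (camera adjusted p = 8.1e-14, and adjusted p = 0.089 with an estimated correlation). Of the macrophage and monocyte markers, 22 of the 26 tested members rose, 0 fell and 4 did not pass (22 and 1 adjusted over the list alone). Members included the protease Ctss 3.60 ± 0.35, Cd68 3.31 ± 0.33 and the complement component C1qb 2.68 ± 0.28 (camera adjusted p = 2.1e-11, and adjusted p = 0.089 with an estimated correlation). For MHC class II presentation, 12 of the 12 tested members rose, 0 fell and 0 did not pass (12 and 0 adjusted over the list alone). Members included H2-Ab1 2.94 ± 0.25 and Cd74 3.96 ± 0.34 (camera adjusted p = 6.2e-09, and adjusted p = 0.089 with an estimated correlation). Of the neutrophil markers, 9 of the 12 tested members rose, 0 fell and 3 did not pass (11 and 0 adjusted over the list alone). Members included the calprotectin subunits S100a8 4.92 ± 0.83 and S100a9 5.37 ± 0.95 (camera adjusted p = 2.2e-04, and adjusted p = 0.17 with an estimated correlation). Haemoglobin transcripts took 14.6 ± 5.69% of counts in aged and 4.24 ± 2.58% in young ovaries, and counts can be shared between near-identical haemoglobin genes. Of the red blood cell genes, 8 of the 9 tested members rose, 0 fell and 1 did not pass (8 and 0 adjusted over the list alone); camera adjusted p = 0.0021, and adjusted p = 0.49 with an estimated correlation. Endothelial markers such as Plvap 1.99 ± 0.29 and Vwf 1.88 ± 0.36 also rose: 6 of the 15 tested members rose, 0 fell and 9 did not pass (10 and 0 adjusted over the list alone); camera adjusted p = 0.0079, and adjusted p = 0.29 with an estimated correlation. In experiment 2 the endothelial list (15 tested, 0 up and 0 down, 0 and 0 adjusted over the list alone) did not pass (camera adjusted p = 0.21). S100a9 changed by 6.33 without young replicate 4.

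Secreted factors, interferon-stimulated genes and sensors of nucleic acids rose too. Of the senescence-associated secretory factors, 24 of the 33 tested members rose, 1 fell and 8 did not pass (25 and 1 adjusted over the list alone). Members included the adhesion molecule Icam1 2.93 ± 0.23, the chemokines Ccl5 4.48 ± 0.41 and Ccl4 4.97 ± 0.48, and Spp1 4.84 ± 0.47 (camera adjusted p = 1.6e-10, and adjusted p = 0.089 with an estimated correlation). The chemokines Ccl2 and Cxcl10 changed by 4.38 ± 0.63 and 5.28 ± 0.70, and Cxcl10 stood at 79.4 ± 50.3 against 1.97 ± 0.883 CPM. Of the interferon-stimulated genes, 30 of the 38 tested members rose, 0 fell and 8 did not pass (30 and 0 adjusted over the list alone). Members included Irf9 1.72 ± 0.20, the immunoproteasome subunit Psmb8 2.34 ± 0.30 and Isg15 1.70 ± 0.41 (camera adjusted p = 1.0e-09, and adjusted p = 0.27 with an estimated correlation). For cytosolic nucleic acid sensing, 12 of the 17 tested members rose, 1 fell and 4 did not pass (13 and 1 adjusted over the list alone). Members included Tmem173, which encodes STING, at 2.03 ± 0.20 and Zbp1 3.08 ± 0.47 (camera adjusted p = 1.7e-05, and adjusted p = 0.13 with an estimated correlation). Of the NF-kB pathway genes, 16 of the 24 tested members rose, 0 fell and 8 did not pass (18 and 1 adjusted over the list alone). Members included Nfkb2 2.67 ± 0.29 and Vcam1 2.31 ± 0.31 (camera adjusted p = 5.3e-07, and adjusted p = 0.089 with an estimated correlation). Among cell cycle arrest and senescence genes, 6 of the 18 tested members rose, 1 fell and 11 did not pass (6 and 1 adjusted over the list alone) and the list did not pass (camera adjusted p = 0.24). In it the CDK inhibitors Cdkn1a 1.17 ± 0.24 and Cdkn2a 2.06 ± 0.36 rose and Hmgb2 -1.88 ± 0.27 fell. Without aged replicate 3 Spp1 changed by 4.14, and without young replicate 4 Ccl2 changed by 4.99. Il6 had 13 counts over experiment 1 and was not tested.

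**Figure D1:**
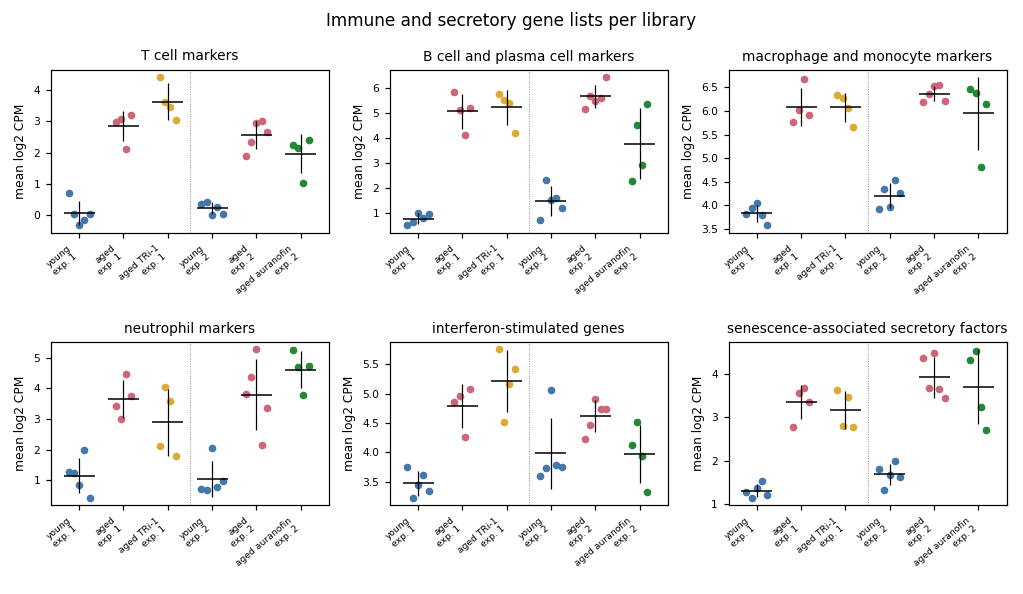
Mean log2 CPM of 6 immune and secretory gene lists (y axis) in each library (dots), by group (x axis), with the group mean (horizontal line) and SD (vertical line) and a dotted line between experiments. Senescence-associated secretory factors stood at 1.31 ± 0.15 in young and 3.35 ± 0.39 in aged ovaries of experiment 1, and at 1.69 ± 0.24 and 3.92 ± 0.47 in experiment 2.

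Oocyte, granulosa cell and proliferation genes were lower in aged ovaries of experiment 1. Of the oocyte genes, 0 of the 22 tested members rose, 21 fell and 1 did not pass (0 and 21 adjusted over the list alone), with a median change of -6.98, or -5.78 when the 7 members without a count in 1 of the groups are set at their bound (camera adjusted p = 5.9e-19, and adjusted p = 0.063 with an estimated correlation). Nlrp5, a maternal-effect protein of the oocyte cortex, was lower by a ratio of 799 (95% counting interval 143 to 31551), and the oocyte growth factor Bmp15 by 694 (95% counting interval 125 to 27415). Granulosa and cumulus cell markers fell: 1 of the 18 tested members rose, 7 fell and 10 did not pass (2 and 11 adjusted over the list alone). Members included the estrogen receptor Esr2 -4.88 ± 0.74, the gap junction gene Gja1 -2.19 ± 0.35, the granulosa transcription factor Foxl2 -1.70 ± 0.34 and Inha -2.91 ± 0.63 (camera adjusted p = 0.011, and adjusted p = 0.33 with an estimated correlation). Of the proliferation genes, 0 of the 28 tested members rose, 15 fell and 13 did not pass (0 and 16 adjusted over the list alone). Members included Cenpf -2.87 ± 0.41 and Cdk1 -2.95 ± 0.45 (camera adjusted p = 5.2e-06, and adjusted p = 0.16 with an estimated correlation). Ribosomal protein genes took 30.0 ± 2.25% of counts in young and 20.1 ± 2.27% in aged ovaries, and processed pseudogenes 1.69 ± 0.387% in young and 0.715 ± 0.229% in aged ovaries. Inha changed by -3.80 without aged replicate 1.

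NRF2 target genes rose in experiment 1, while Txnrd1 did not pass. Of these oxidative stress genes, 13 of the 28 tested members rose, 1 fell and 14 did not pass (15 and 1 adjusted over the list alone). Members included the haem-degrading Hmox1 3.38 ± 0.38 (80.7 ± 18.0 against 7.80 ± 3.58 CPM), sulfiredoxin Srxn1 2.98 ± 0.34 and the ferritin subunits Ftl1 2.03 ± 0.18 and Fth1 1.64 ± 0.18 (camera adjusted p = 0.0012, and adjusted p = 0.29 with an estimated correlation). Txnrd1 stood at 35.5 ± 11.8 against 20.3 ± 4.06 CPM, a value of 0.81 ± 0.31 with adjusted p = 0.0520, and 0.017 without aged replicate 1 (ENSMUSG00000020250, chromosome 10, 82833951 to 82897712). Nqo1 stood at -0.75 ± 0.46 (adjusted p = 0.22). Among thioredoxin, peroxiredoxin and glutathione enzymes, 4 of the 25 tested members rose, 3 fell and 18 did not pass (4 and 3 adjusted over the list alone). Members included Prdx4 -1.71 ± 0.21 and Gpx3 1.56 ± 0.32 (camera adjusted p = 0.67).

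The other lists did not pass camera in experiment 1. Extracellular matrix and fibrosis genes came closest: 13 of the 31 tested members rose, 3 fell and 15 did not pass (13 and 3 adjusted over the list alone). Members included fibronectin, Fn1 3.36 ± 0.44, and biglycan, Bgn 1.65 ± 0.25 (camera adjusted p = 0.076). For steroid hormone synthesis, 1 of the 18 tested members rose, 4 fell and 13 did not pass (1 and 4 adjusted over the list alone). Members included Nr5a2 -4.93 ± 1.04 and Hsd3b1 -2.00 ± 0.47 (camera adjusted p = 0.079). Of the hepatic acute phase genes, 5 of the 21 tested members rose, 0 fell and 16 did not pass (5 and 0 adjusted over the list alone). Members included C3 2.31 ± 0.28 and Saa3 3.68 ± 0.71 (camera adjusted p = 0.091). Stress and unfolded protein response genes went both ways: 8 of the 25 tested members rose, 6 fell and 11 did not pass (8 and 6 adjusted over the list alone). Members included Hsp90b1 -2.63 ± 0.32 and Atf4 1.302 ± 0.22 (camera adjusted p = 0.68). Of the hepatocyte markers, 3 of the 29 tested members rose, 1 fell and 25 did not pass (3 and 1 adjusted over the list alone); their median was 1.22 and their mean 0.94, while camera pointed down (camera adjusted p = 0.87). Aged replicate 3 stood at a mean log2 CPM of 5.09 for these markers against 2.54 ± 0.73 in young ovaries. Without it Arg1 4.29 ± 0.86, an arginase of hepatocytes and macrophages, changed by 1.69, Fn1 by 2.69 and Nr5a2 by -5.81. Saa3 changed by 4.58 without young replicate 5. Of the mitochondrial respiratory chain genes, 3 of the 37 tested members rose, 10 fell and 24 did not pass (3 and 12 adjusted over the list alone). Members included Atp5c1 -1.70 ± 0.19 and Uqcrc1 1.68 ± 0.21 (camera adjusted p = 0.13). Immediate early genes (19 tested, 5 up and 1 down, 5 and 1 adjusted over the list alone) included Junb 2.39 ± 0.38 (camera adjusted p = 0.13), and circadian clock genes (18 tested, 5 up and 0 down, 5 and 0 adjusted over the list alone) included Bhlhe41 2.09 ± 0.36 (camera adjusted p = 0.42).

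The remaining lists, mostly of other cell types, did not pass camera in experiment 1 either, with kidney markers too few to test. Adipocyte markers (16 tested, 4 up and 0 down, 1 and 0 adjusted over the list alone) had a median of 0.70 (camera adjusted p = 0.26). Theca and stromal markers (15 tested, 2 up and 3 down, 2 and 3 adjusted over the list alone) included Mgp 1.33 ± 0.17 and Ogn -0.98 ± 0.24; their median was 0.05, while their mean was -0.08 and camera pointed down (camera adjusted p = 0.56). Luteal cell markers (15 tested, 1 up and 1 down, 1 and 1 adjusted over the list alone) had a median of -0.37 (camera adjusted p = 0.61), and muscle markers (13 tested, 1 up and 2 down, 1 and 2 adjusted over the list alone) one of -0.21 (camera adjusted p = 0.66). Oviduct and uterine epithelium markers (17 tested, 3 up and 1 down, 2 and 1 adjusted over the list alone) had a median of 0.46 (camera adjusted p = 0.41). Hepatic drug and bile acid metabolism genes (15 tested, 1 up and 0 down, 1 and 0 adjusted over the list alone) gave camera adjusted p = 0.61 and lung epithelium markers (9 tested, 1 up and 0 down, 1 and 0 adjusted over the list alone) gave camera adjusted p = 0.61. Kidney epithelium markers (4 tested, 0 up and 1 down, 0 and 1 adjusted over the list alone) were too few for camera and had a median of -0.60. Cholesterol synthesis genes (22 tested, 2 up and 1 down, 1 and 0 adjusted over the list alone) had a median of 0.01 while camera pointed down (camera adjusted p = 0.72).

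In all, 2958 genes were higher and 2632 lower in aged ovaries of experiment 1 among 16028 tested with edgeR. Of the called genes, 3289 with a mean of at least 5 CPM did not overlap between the groups (135 of them carry no usable name). Chance gives 1.59% of unselected genes, but called genes were picked for a difference between the same groups. Their separation is therefore no further support. Without young replicate 5, aged replicate 3 and TRi-1 replicate 1, the count of 5590 became 3968, and without young replicate 3 and aged replicate 1 it became 5090. Camera called 12 lists up and 3 down of 33, of which 0 passed with an estimated correlation (lowest adjusted p = 0.063).

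Experiment 2 repeated the comparison in other mice, 5 aged and 5 young. Neutrophil, lymphocyte and macrophage transcripts were again higher in aged ovaries and proliferation and oocyte transcripts lower. S100a8 stood at 939 ± 845 against 3.55 ± 2.22 CPM (aged against young), a change of 8.04 ± 0.89, and Il1b at 87.8 ± 62.7 against 0.929 ± 0.477 CPM, a change of 6.52 ± 0.75. Vcam1, an adhesion molecule for leukocytes, changed by 3.60 ± 0.35, and Hmgb2, a chromatin protein lost in senescent cells, by -1.61 ± 0.23. Each of these 4 had an edgeR adjusted p of at most 5.2e-04.

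Of the largest rises, the neutrophil granule gene Ngp was at least 235.2-fold higher and the chemokine Cxcl2 higher by a ratio of 451 (95% counting interval 125 to 3725). The others were Ighg2c 9.85 ± 1.54, Ighg3 7.71 ± 1.74, the lectin receptor Clec4e 8.46 ± 1.16, Glycam1 8.43 ± 1.09, S100a8 and S100a9 7.92 ± 0.86. Among the largest falls, Tcea1-ps1, a pseudogene whose reads may come from its parent gene, was at least 304.7-fold lower. The small nucleolar RNAs Snord89 -6.06 ± 0.92 and Snora30 -3.38 ± 0.60, which lie inside other genes, the mitotic genes Kif20b -3.47 ± 0.44 and Aspm -2.63 ± 0.48, and fibrillin Fbn2 -2.63 ± 0.55 followed. Dcpp3 -4.86 ± 1.32 and Slc38a5 -3.62 ± 0.94 completed the 8 largest falls under the rule, which asks for no overlap and at least 5 CPM. Dcpp3 lost its call without young replicate 4 (adjusted p = 0.0527) or aged replicates 1 (0.061), 3 (0.057), 4 (0.069) or 5 (0.060), and changed by -5.78 without aged replicate 2. Slc38a5 lost it without young replicate 1 (0.0524) or aged replicates 2 (0.0512), 3 (0.057) or 4 (0.056). Aged replicate 3 moved several neutrophil-related genes: without it the changes were 7.76 for Clec4e, 7.43 for S100a8 and 7.12 for S100a9. All 6 young counts of Clec4e came from replicate 4, all 7 of Glycam1 from replicate 3 and both of Cxcl2 from replicate 1, so without that library the young group held 0. S100a9 changed by 8.52 without young replicate 3. Without young replicate 2, Ighg2c, Ighg3 and Snord89 changed by 11.78, 9.08 and -4.88. Ighg3 and Glycam1 changed by 6.38 and 7.82 without aged replicate 5, and Snora30 by -3.98 without aged replicate 2.

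Immune lists rose in experiment 2 as well. Of the T cell markers, 16 of the 24 tested members rose, 0 fell and 8 did not pass (22 and 0 adjusted over the list alone). Members included Cd3e 4.97 ± 0.65 and the cytotoxic granule gene Gzmk, at least 51.37-fold higher (camera adjusted p = 1.2e-16, and adjusted p = 0.042 with an estimated correlation). For B cell and plasma cell markers, 19 of the 26 tested members rose, 0 fell and 7 did not pass (25 and 0 adjusted over the list alone). Members included Ighm 6.91 ± 0.59 and Jchain 4.99 ± 0.63 (camera adjusted p = 6.1e-21, and adjusted p = 0.065 with an estimated correlation). Of the macrophage and monocyte markers, 21 of the 26 tested members rose, 0 fell and 5 did not pass (23 and 0 adjusted over the list alone). Members included Ctss 3.03 ± 0.41 and Cd68 2.69 ± 0.37 (camera adjusted p = 1.2e-16, and adjusted p = 0.058 with an estimated correlation). Of the neutrophil markers, 7 of the 15 tested members rose, 0 fell and 8 did not pass (8 and 0 adjusted over the list alone); camera adjusted p = 8.5e-08, and adjusted p = 0.10 with an estimated correlation. Of the MHC class II genes, 9 of the 12 tested members rose, 0 fell and 3 did not pass (12 and 0 adjusted over the list alone). Members included H2-Ab1 1.98 ± 0.36 (camera adjusted p = 1.3e-09, and adjusted p = 0.10 with an estimated correlation). Senescence-associated secretory factors rose: 23 of the 33 tested members rose, 1 fell and 9 did not pass (26 and 1 adjusted over the list alone). Members included the neutrophil chemokine Cxcl5 6.67 ± 0.72, Icam1 2.88 ± 0.35 and Ccl2 5.06 ± 0.85 (camera adjusted p = 1.6e-16, and adjusted p = 0.042 with an estimated correlation). Of the NF-kB pathway genes, 13 of the 24 tested members rose, 0 fell and 11 did not pass (15 and 0 adjusted over the list alone). Members included Nfkbie 3.11 ± 0.35 and Nfkb2 1.63 ± 0.26 (camera adjusted p = 3.5e-11, and adjusted p = 0.042 with an estimated correlation). For nucleic acid sensing, 6 of the 18 tested members rose, 0 fell and 12 did not pass (9 and 0 adjusted over the list alone). Members included Samhd1 1.25 ± 0.19 and Ikbke 1.72 ± 0.33 (camera adjusted p = 3.0e-05, and adjusted p = 0.19 with an estimated correlation). Haemoglobin took 4.05 ± 1.69% of counts in aged and 1.77 ± 1.98% in young ovaries, and of the red blood cell genes 2 of the 9 tested members rose, 0 fell and 7 did not pass (3 and 0 adjusted over the list alone); camera adjusted p = 3.2e-04, and adjusted p = 0.37 with an estimated correlation.

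Of the interferon-stimulated genes, 6 of the 38 tested members rose, 0 fell and 32 did not pass (8 and 0 adjusted over the list alone). Members included Psmb8 1.80 ± 0.35 and Gbp2 1.75 ± 0.39 (camera adjusted p = 9.2e-05, and adjusted p = 0.41 with an estimated correlation). Young replicate 3 stood at a mean log2 CPM of 5.06 for this list, above the other 4 young libraries at 3.59 to 3.78. Isg15 stood at 1.11 ± 0.46 with adjusted p = 0.15, and 0.0460 without that library. Cxcl10 rose by 3.83 ± 0.72, and by 4.49 without young replicate 4. Cdkn1a rose by 1.26 ± 0.24 and Cdkn2a by 2.96 ± 0.80 (adjusted p = 0.026). The Cdkn2a call ended without young replicate 1 (adjusted p = 0.063) or aged replicate 1 (0.056), and its value was 3.56 without young replicate 4. Il6 had 54 counts over experiment 2 and was not tested. Acute phase genes rose (13 tested, 3 up and 1 down, 6 and 1 adjusted over the list alone), with Saa3 6.18 ± 0.75 and C3 2.08 ± 0.30 (camera adjusted p = 8.6e-04, and adjusted p = 0.069 with an estimated correlation), and immediate early genes rose (19 tested, 5 up and 0 down, 5 and 0 adjusted over the list alone), with Zfp36 1.63 ± 0.25 (camera adjusted p = 0.0015, and adjusted p = 0.22 with an estimated correlation). Stress and unfolded protein response genes passed upwards (25 tested, 4 up and 1 down, 7 and 2 adjusted over the list alone), although Hsp90b1 -1.65 ± 0.39 fell (camera adjusted p = 0.040, and adjusted p = 0.35 with an estimated correlation). That call ended without young replicates 1 (0.079), 4 (0.060) or 5 (0.098) or aged replicates 1 (0.077) or 2 (0.066).

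Proliferation genes fell in experiment 2: 0 of the 28 tested members rose, 5 fell and 23 did not pass (0 and 10 adjusted over the list alone). Members included Top2a -1.77 ± 0.29 and Cenpf -1.65 ± 0.28 (camera adjusted p = 5.6e-05, and adjusted p = 0.23 with an estimated correlation). Of the oocyte genes, 0 of the 18 tested members rose, 11 fell and 7 did not pass (0 and 15 adjusted over the list alone), with a median of -4.22, the same with 2 members at their bound (camera adjusted p = 2.0e-08, and adjusted p = 0.23 with an estimated correlation). Zar1 was lower by a ratio of 162 (95% counting interval 55.5 to 787) and the zona pellucida gene Zp2 was at least 89.96-fold lower. Young replicate 3 stood at a mean log2 CPM of -1.72 for oocyte genes, against 1.47 to 2.48 in the other young libraries. Granulosa markers (20 tested, 0 up and 3 down, 0 and 4 adjusted over the list alone) included Foxl2 -1.74 ± 0.42 and did not pass as a list (camera adjusted p = 0.18). Young replicate 3 was also low in them, at 1.79 against 3.41 to 4.05 in the other young libraries. Without that library camera called 18 lists with age in place of 15. Of the NRF2 target genes, 4 of the 28 tested members rose, 0 fell and 24 did not pass (6 and 1 adjusted over the list alone). Members included Hmox1 1.87 ± 0.32, Srxn1 1.40 ± 0.27 and Fth1 1.98 ± 0.28, and the list did not pass (camera adjusted p = 0.066). Txnrd1 stood at 53.5 ± 20.2 against 46.6 ± 33.5 CPM, a value of 0.20 ± 0.47 (adjusted p = 0.86), and Nqo1 at -0.24 ± 0.44 (adjusted p = 0.81). The young mean of Txnrd1 was raised by young replicate 3, at 104.9 CPM against 22.4 to 41.4 in the other young libraries. Its value of 0.20 thus depends on that library.

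In experiment 2, 956 genes were higher and 749 lower in aged ovaries among 16309 tested with edgeR. Of the called genes, 1120 with a mean of at least 5 CPM did not overlap between the groups (45 without a usable name). Chance gives 0.794% of unselected genes, and called genes separate largely by selection. Without young replicate 3 and auranofin replicate 3, which stood apart in tissue markers, the count of 1705 became 2059, and without young replicates 2 and 3 and auranofin replicates 3 and 4 it became 2543. The 749 lower genes became 462 without young replicate 1, 491 without young replicate 2, 464 without aged replicate 1 and 491 without aged replicate 4. Camera called 13 lists up and 2 down of 34, of which 3 passed with an estimated correlation.

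Both experiments together gave 3054 genes higher and 3119 lower with age among 17484 tested, and the total of 6173 became 6607 without young and auranofin replicates 3 of experiment 2. Over both, the named genes stood at Icam1 2.89 ± 0.22, Il1b 6.47 ± 0.55, Hmox1 2.62 ± 0.26, Srxn1 2.18 ± 0.23, Cdkn1a 1.21 ± 0.17, Cdkn2a 2.49 ± 0.44, Isg15 1.39 ± 0.33 and Foxl2 -1.73 ± 0.29, each with an edgeR adjusted p of at most 0.0015. Txnrd1 stood at 0.49 ± 0.30 with adjusted p = 0.21, a value that includes the high level in young replicate 3 of experiment 2. Of the genes called in experiments 1 and 2, 805 were higher in both against 175.9 by chance, 615 were lower in both against 117.8, and 1 was called in opposite directions against 288.1. Across 15512 genes tested in both, which are not independent replicates, the age effects correlated with Pearson's r = 0.752 and Spearman's rho = 0.659, and 73.3% had the same sign. No gene passed edgeR's test of a difference in the age effect between experiments: 0 were called, 2067 had an unadjusted p under 0.05, DESeq2 called 96 up and 83 down, and limma-voom 21 up and 12 down. That count became 7 without young replicate 4 of experiment 1, 2 without aged replicate 2 or 3 of experiment 1, 1 without young replicate 3 of experiment 2 and 19 without young replicate 4 of experiment 2.

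**Figure D2:**
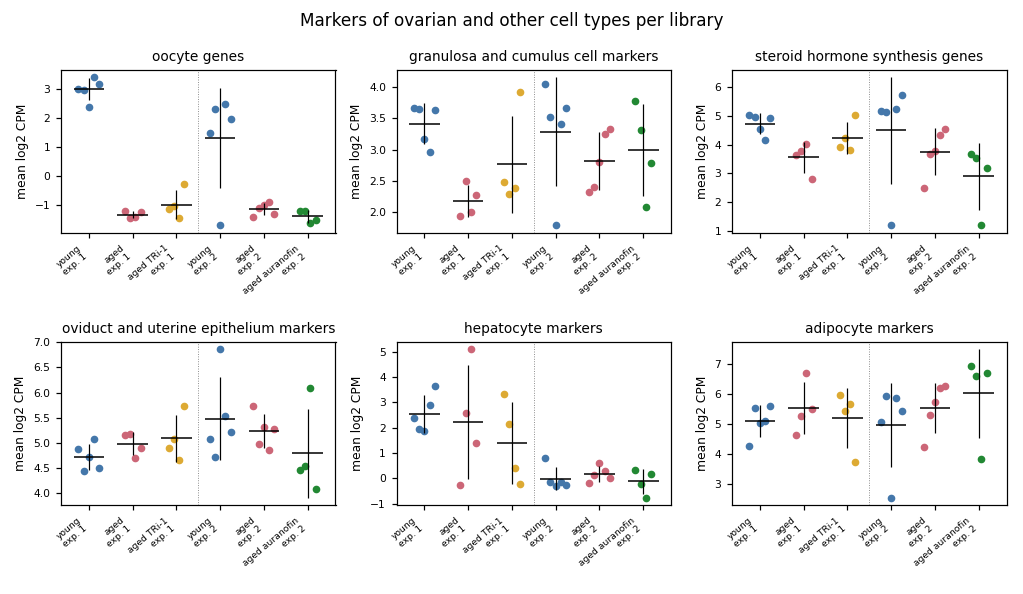
Mean log2 CPM of 6 lists of ovarian and other cell type markers (y axis) in each library (dots), by group (x axis), with the group mean (horizontal line) and SD (vertical line) and a dotted line between experiments. Young replicate 3 of experiment 2 stood at 1.2 for steroid hormone synthesis genes, against 5.14 to 5.73 in the other young libraries.

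The next comparison asks what TRi-1 changed in the aged ovary (n = 4 treated and 4 untreated). Few genes passed, among them the matrix genes Fn1 and Mfap5, and no list gene for antioxidant, interferon or NRF2 functions passed the test. Fn1, which encodes fibronectin, fell from 714.6 ± 541 to 140 ± 68.9 CPM, a change of -2.36 ± 0.46 (adjusted p = 0.039; ENSMUSG00000026193, chromosome 1, 71585520 to 71653200). Pi16, a marker of adventitial fibroblasts, changed by -2.30 ± 0.37 (adjusted p = 0.026) and Mfap5, a microfibril protein, by -1.36 ± 0.27 (adjusted p = 0.042). The calls depended on single libraries: of the 67 genes called, 0 passed without aged replicate 3, without TRi-1 replicate 1 or without TRi-1 replicate 4.

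The other named falls were the triglyceride synthesis enzyme Dgat2 -2.08 ± 0.37, Nnat -1.95 ± 0.37, Anxa11 -1.40 ± 0.24, the growth factor Bmp4 -1.39 ± 0.29 and Tlnrd1 -1.37 ± 0.19. Named rises were Cnmd 2.92 ± 0.52, the phosphatase subunit Ppp2r2c 2.27 ± 0.40, the T-box factor Tbx3 1.65 ± 0.33, Nipal1 1.62 ± 0.32, the zinc finger gene Zfp131 1.496 ± 0.26 and the deubiquitinase Usp25 1.49 ± 0.30. Rpl18-ps2 5.49 ± 1.15 and Amd-ps3 1.68 ± 0.29 are pseudogenes, whose reads may come from their parent genes. Processed pseudogenes took 1.135 ± 0.182% of counts in treated and 0.715 ± 0.229% in untreated aged ovaries, and haemoglobin 9.65 ± 3.47 and 14.6 ± 5.69%. Adjusted p for these genes ran from 0.026 to 0.0467. The rule named only genes whose 4 treated libraries did not overlap the 4 untreated ones, so that separation adds no support. Without aged replicate 3, which stood apart in hepatocyte markers, Fn1 stood at -1.69 (adjusted p = 0.093). Whether liver RNA in that library adds to the fall of Fn1 was not tested. Without aged replicate 4 Rpl18-ps2 stood at 9.49 (adjusted p = 0.060). The smallest adjusted p of any gene without aged replicate 3 was 0.058.

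Extracellular matrix and fibrosis genes passed camera downwards under TRi-1 at the preset correlation: 0 of the 31 tested members rose, 1 fell and 30 did not pass (0 and 14 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 1.3e-04, and adjusted p = 0.87 with an estimated correlation). Col4a2 stood at -0.93 ± 0.22 and Fbn1 at -1.02 ± 0.27, with adjusted p = 0.065 and 0.084. This list passed camera with each library left out in turn. Senescence-associated secretory factors passed downwards, although 0 of the 33 tested members rose, 0 fell and 33 did not pass (1 and 4 adjusted over the list alone); camera adjusted p = 0.029, and adjusted p = 0.87 with an estimated correlation. Timp1 stood at -1.54 ± 0.37 (adjusted p = 0.066), Il1b at -2.14 ± 0.57 (0.087) and Spp1 at -1.45 ± 0.43 (0.11), while Ccl5 stood at 1.61 ± 0.39 (0.067). That list call ended without aged replicates 2 (0.093), 3 (0.13) or 4 (0.081) or TRi-1 replicates 2 (0.34) or 4 (0.26). Neutrophil markers passed downwards with 0 of 12 members called, over all genes or adjusted over the list alone, and a median of -0.62 (camera adjusted p = 0.019, and adjusted p = 0.87 with an estimated correlation). T cell markers passed upwards with 0 of 24 called on either basis and a median of 0.49 (camera adjusted p = 0.029, and adjusted p = 0.87 with an estimated correlation). The neutrophil call ended without aged replicate 3 (0.11) or TRi-1 replicate 4 (0.12) and the T cell call without aged replicate 3 (0.43) or TRi-1 replicate 1 (0.35).

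Further cell type lists passed camera under TRi-1 at the preset correlation without a member called over all genes. Hepatocyte markers passed downwards with 0 of 29 members called on either basis and a median of -1.80 (camera adjusted p = 0.012, and adjusted p = 0.87 with an estimated correlation). Aged replicate 3 stood at 5.09 for them, and the call ended without it (0.73) or TRi-1 replicate 4 (0.24). Acute phase genes (21 tested, 0 up and 0 down, 0 and 3 adjusted over the list alone) also passed downwards, with Saa3 at -2.60 ± 0.74 (camera adjusted p = 0.012, and adjusted p = 0.87 with an estimated correlation), and that call ended without the same libraries (0.41 and 0.11). Adipocyte markers (16 tested, 0 up and 0 down, 0 and 0 adjusted over the list alone) passed downwards with a median of -0.67 (camera adjusted p = 0.029, and adjusted p = 0.87 with an estimated correlation), and the call ended without aged replicate 3 (0.43) or TRi-1 replicate 4 (0.60). Endothelial markers (15 tested, 0 up and 0 down, 0 and 0 adjusted over the list alone) passed downwards with a median of -0.44 (camera adjusted p = 0.029, and adjusted p = 0.87 with an estimated correlation), and the call ended without aged replicate 3 (0.11) or TRi-1 replicate 4 (0.21). Granulosa and cumulus cell markers passed upwards (18 tested, 0 up and 0 down, 3 and 0 adjusted over the list alone), with Foxl2 at 1.53 ± 0.35 and Inha at 1.96 ± 0.63 (camera adjusted p = 0.038, and adjusted p = 0.87 with an estimated correlation). TRi-1 replicate 4 stood at a mean log2 CPM of 3.92 for granulosa markers, above the other 3 at 2.29 to 2.48, and the call ended without it (0.60) or without aged replicate 1 (0.090) or 3 (0.13).

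Other lists did not pass under TRi-1. NRF2 target genes (28 tested, 0 up and 0 down, 1 and 1 adjusted over the list alone) had a median of -0.01 and a mean of 0.16 (camera adjusted p = 0.84). Txnrd1 itself stood at 47.1 ± 23.0 against 35.5 ± 11.8 CPM, a value of 0.41 ± 0.32 (adjusted p = 0.57), with Nqo1 at 1.3 ± 0.47, Srxn1 at -0.21 ± 0.34 and Hmox1 at -0.70 ± 0.37, and none of these passed. Interferon-stimulated genes (38 tested, 0 up and 0 down, 0 and 0 adjusted over the list alone) had a median of 0.14 (camera adjusted p = 0.42), with Isg15 at -0.03 ± 0.42 and Cxcl10 at 0.55 ± 0.60, neither of which passed. Macrophage markers (26 tested, 0 up and 0 down, 0 and 1 adjusted over the list alone) had a median of -0.39 (camera adjusted p = 0.17), NF-kB genes (24 tested, 0 up and 0 down, 0 and 1 adjusted over the list alone) one of -0.03 (camera adjusted p = 0.84), and B cell and plasma cell markers (26 tested, 0 up and 0 down, 0 and 0 adjusted over the list alone) one of -0.21 (camera adjusted p = 0.60). MHC class II genes (12 tested, 0 up and 0 down, 0 and 0 adjusted over the list alone) had a median of 0.00, a mean of -0.08 and camera pointing down (camera adjusted p = 0.64). Cdkn1a stood at -0.76 ± 0.26, Cdkn2a at 0.50 ± 0.36 and Ccl2 at -0.51 ± 0.55, and none of them passed.

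In edgeR, 28 genes were higher and 39 lower with TRi-1 among 16028 tested, with 2650 at an unadjusted p under 0.05. DESeq2 called 270 up and 310 down, and limma-voom 24 up and 73 down. With only the 2 groups compared edgeR called 0 genes, and with all 27 libraries in 1 fit it called 2. Camera called 2 lists up and 7 down of 33, of which 0 passed with an estimated correlation. Of the called genes 65 had a mean of at least 5 CPM and did not overlap between the groups (3 without a usable name). For unselected genes chance gives 2.86%, and called genes separate largely by selection. The count was 0 without young replicate 5, aged replicate 3 and TRi-1 replicate 1 together and 67 without young replicate 3 and aged replicate 1. Leaving out single libraries gave 32 (aged replicate 1), 164 (aged 2), 22 (aged 4), 12 (TRi-1 2) and 22 (TRi-1 3) beside the 3 that gave 0.

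The auranofin comparison asks what that drug changed in the aged ovary (n = 4 treated and 5 untreated). Oxidative stress genes under NRF2 rose. Hmox1, the haem oxygenase, stood at 710.4 ± 333 against 40.8 ± 2.51 CPM (treated against untreated), a change of 4.12 ± 0.36 (adjusted p = 7.5e-05; ENSMUSG00000005413, chromosome 8, 75093621 to 75100589). Srxn1, which repairs oxidised peroxiredoxins, stood at 347 ± 139.9 against 64.6 ± 8.48 CPM, a change of 2.42 ± 0.28 (ENSMUSG00000032802, chromosome 2, 152105516 to 152111376). Gclm, a subunit of the enzyme that limits glutathione synthesis, stood at 118 ± 37.9 against 26.0 ± 3.07 CPM, a change of 2.18 ± 0.26 (ENSMUSG00000028124, chromosome 3, 122245557 to 122270732). Both had an edgeR adjusted p of 0.0020, and for all 3 genes the lowest treated library lay above the highest untreated one.

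Of the NRF2 target genes, 3 of the 28 tested members rose, 0 fell and 25 did not pass (13 and 0 adjusted over the list alone), with a median of 0.97 (camera adjusted p = 7.8e-14, and adjusted p = 0.0029 with an estimated correlation). Txnrd1 stood at 199 ± 107 against 53.5 ± 20.2 CPM, a value of 1.90 ± 0.50 with adjusted p = 0.41. In 3 auranofin libraries it stood at 283, 257 and 212 CPM and in replicate 4 at 44.5 CPM, within the untreated range of 36.1 to 85.1. Nqo1 stood at 2.01 ± 0.46 (adjusted p = 0.38), with 4.38 CPM in replicate 4 against 12.2 to 20.6 in the others, and Gclc at 1.55 ± 0.30 (0.27). DESeq2 called these 3 genes (adjusted p = 0.041, 0.019 and 0.0051), as did limma-voom. The next smallest p belonged to the translation repressor Eif4ebp1 at 1.16 ± 0.19 (adjusted p = 0.059) and the peroxisome gene Pex6 at -1.81 ± 0.30 (0.067).

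**Figure D3:**
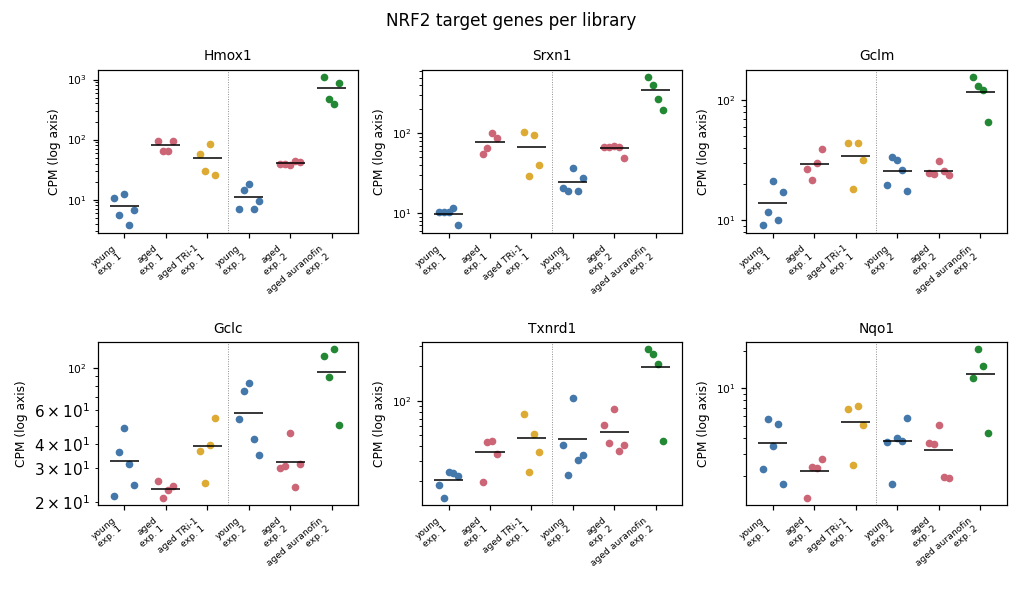
CPM of 6 NRF2 target genes (y axis, log scale) in each library (dots), by group (x axis), with the group mean (horizontal line) and a dotted line between experiments. Hmox1 stood at 391 to 1098 CPM in the 4 auranofin libraries, all above the 5 aged untreated libraries of experiment 2 at 38.4 to 44.3.

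Immune lists passed downwards under auranofin without a called member. Of 38 interferon-stimulated genes 0 were called, over all genes or adjusted over the list alone, with a median of -0.47 (camera adjusted p = 2.8e-07, and adjusted p = 0.61 with an estimated correlation). Isg15 stood at -1.29 ± 0.50, Oasl2 at -0.89 ± 0.26 and Psmb10 at -0.69 ± 0.23, each with an adjusted p of at least 0.46. B cell and plasma cell markers (26 tested, 0 up and 0 down, 0 and 0 adjusted over the list alone) had a median of -1.23, with Ighm at -1.197 ± 0.49 (camera adjusted p = 3.8e-13, and adjusted p = 0.52 with an estimated correlation). The mean log2 CPM of this list was 2.25, 4.52, 2.92 and 5.37 in the 4 auranofin libraries against 5.66 ± 0.48 in untreated ones. T cell markers (24 tested, 0 up and 0 down, 0 and 0 adjusted over the list alone) had a median of -0.47 (camera adjusted p = 0.0017, and adjusted p = 0.64 with an estimated correlation), MHC class II genes (12 tested, 0 up and 0 down, 0 and 0 adjusted over the list alone) one of -0.50 (camera adjusted p = 1.9e-04, and adjusted p = 0.61 with an estimated correlation) and NF-kB genes (24 tested, 0 up and 0 down, 0 and 0 adjusted over the list alone) one of -0.41 (camera adjusted p = 0.015, and adjusted p = 0.64 with an estimated correlation). Proliferation genes (28 tested, 0 up and 0 down, 0 and 0 adjusted over the list alone) passed downwards, with a median of -0.43 (camera adjusted p = 1.8e-04, and adjusted p = 0.61 with an estimated correlation). Neutrophil markers (15 tested, 0 up and 0 down, 0 and 0 adjusted over the list alone) passed upwards, with a median of 0.71 and S100a8 at 0.96 ± 0.68 (camera adjusted p = 0.019, and adjusted p = 0.64 with an estimated correlation). The T cell call ended without auranofin replicate 3 (0.21), and the NF-kB call without aged replicate 3 (0.083) or auranofin replicate 4 (0.079). The neutrophil call ended without aged replicates 4 (0.17) or 5 (0.0529) or auranofin replicates 1 (0.085), 2 (0.072) or 4 (0.079). Without young replicate 3 and auranofin replicate 3 together the T cell, MHC class II and NF-kB calls ended (0.23, 0.058 and 0.0527).

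Tissue lists near the threshold also passed under auranofin. Extracellular matrix genes (31 tested, 0 up and 0 down, 0 and 0 adjusted over the list alone) passed upwards with a median of 0.31 and Col4a1 at 0.90 ± 0.26 (camera adjusted p = 0.029, and adjusted p = 0.64 with an estimated correlation). That call ended without aged replicates 4 (0.15) or 5 (0.061), auranofin replicates 1 (0.14), 2 (0.12) or 3 (0.10), or young and auranofin replicates 3 (0.096). Cholesterol synthesis genes (23 tested, 0 up and 0 down, 0 and 0 adjusted over the list alone) passed downwards with a median of -0.31 (camera adjusted p = 0.034, and adjusted p = 0.70 with an estimated correlation), which ended without aged replicate 3 (0.36) or auranofin replicates 1 (0.092), 2 (0.0512) or 4 (0.079). Oviduct and uterine epithelium markers (18 tested, 0 up and 0 down, 0 and 0 adjusted over the list alone) passed downwards with a median of -0.17 and a mean of 0.13 (camera adjusted p = 0.026, and adjusted p = 0.64 with an estimated correlation). That call ended without aged replicate 1 (0.0504) or auranofin replicates 1 (0.12), 2 (0.11) or 4 (0.079). Auranofin replicate 3 stood at a mean log2 CPM of 6.08 for these markers against 4.10 to 4.54 in the other 3. Adipocyte markers (16 tested, 0 up and 0 down, 0 and 0 adjusted over the list alone) had a median of 0.90 (camera adjusted p = 0.080) and steroid hormone synthesis genes (17 tested, 0 up and 0 down, 0 and 0 adjusted over the list alone) one of -0.76 (camera adjusted p = 0.12), so cell content may also differ between the groups. Senescence-associated secretory factors (33 tested, 0 up and 0 down, 0 and 0 adjusted over the list alone) had a median of 0.07, a mean of -0.06 and camera pointing down (camera adjusted p = 0.42). Il1b stood at -0.72 ± 0.61, Ccl2 at -0.56 ± 0.74, Cxcl10 at -0.78 ± 0.68, Cdkn1a at 0.25 ± 0.25 and Cdkn2a at -1.21 ± 0.79, and none passed. Macrophage markers (26 tested, 0 up and 0 down, 0 and 1 adjusted over the list alone) had a median of -0.07 (camera adjusted p = 0.092), and thioredoxin, peroxiredoxin and glutathione enzymes (25 tested, 0 up and 0 down, 2 and 0 adjusted over the list alone) one of 0.19 (camera adjusted p = 0.098).

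In edgeR, 3 genes rose and 0 fell with auranofin among 16309 tested, with 1148 at an unadjusted p under 0.05, while DESeq2 called 33 up and 34 down and limma-voom 21 up and 12 down. Camera called 3 lists up and 8 down of 34, of which 1 passed with an estimated correlation. All 3 genes did not overlap between the groups, where chance gives 1.59% of unselected genes. As called genes they were picked for such a difference, so the separation adds no support. The count was 3 without young replicate 3 and auranofin replicate 3, and 8 without young replicates 2 and 3 and auranofin replicates 3 and 4.

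The effects of both compounds, given in different experiments, were compared by the difference of their effects. Hmox1 differed by 4.81 ± 0.54 (auranofin minus TRi-1, adjusted p = 3.5e-05), the small heat shock gene Hspb8 by 2.13 ± 0.32 (0.0033; ENSMUSG00000041548, chromosome 5, 116408491 to 116422864) and Srxn1 by 2.62 ± 0.46 (0.032). Hspb8 stood at 234 ± 57.1 CPM in aged and 108 ± 13.3 in TRi-1 ovaries of experiment 1, and at 240.4 ± 57.7 in aged and 486 ± 110.4 in auranofin ovaries of experiment 2. These 3 genes were called higher and 0 lower among 17484 tested, with 1900 at an unadjusted p under 0.05. DESeq2 called 45 up and 52 down, and limma-voom 19 up and 11 down. The Srxn1 call ended without aged replicate 3 (0.15) or 4 (0.11) or TRi-1 replicate 2 (0.069) or 4 (0.20) of experiment 1. It also ended without aged replicates 1 (0.074), 2 (0.067), 3 (0.065), 4 (0.066) or 5 (0.073) or auranofin replicates 1 (0.15) or 2 (0.073) of experiment 2. The count was 7 without aged replicate 2 of experiment 1, 5 without TRi-1 replicate 1, 10 without auranofin replicate 4 and 5 without young and auranofin replicates 3 of experiment 2. Across 15512 genes the effects of the compounds correlated with Pearson's r = 0.011 and Spearman's rho = -0.00088, with 50.0% of the same sign, and r ran from -0.044 without auranofin replicate 3 to 0.099 without auranofin replicate 4.

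Whether the treatments moved the genes that change with age was asked with sets called in the other experiment. Of the 956 genes higher with age in experiment 2, 931 were tested with TRi-1, where 646 were lower and 285 higher with a median of -0.25 (camera p = 7.7e-06, and p = 0.17 with an estimated correlation). Of the 749 genes lower with age, 735 were tested, where 586 were higher and 144 lower with a median of 0.40 (camera p = 1.5e-12, and p = 0.14 with an estimated correlation). Without TRi-1 replicate 4, whose granulosa markers stood apart, these camera p were 0.025 and 2.2e-05 and the medians -0.11 and 0.21, and without aged replicate 3 the median of the higher set was -0.12. The age effect of experiment 2 and the TRi-1 effect correlated with r = -0.25 across genes, and with r = -0.068 without TRi-1 replicate 4. The processed pseudogene share of experiment 1 moved the same way (1.69% in young, 0.715% in aged and 1.135% in TRi-1 ovaries). RNA quality was not tested as a source of these shifts. Under auranofin, the 2931 tested genes higher with age in experiment 1 had a median of 0.0033 (camera p = 0.37, with an estimated correlation p = 0.76) and the 2486 tested genes lower with age one of 0.04 (camera p = 0.38, with an estimated correlation p = 0.71). Without auranofin replicate 4 these camera p were 2.0e-04 for the higher set, with a median of -0.15, and 0.021 for the lower set, with a median of 0.085. The age effect of experiment 1 and the auranofin effect correlated with r = -0.027, but with r = 0.067 without auranofin replicate 3 and -0.081 without auranofin replicate 4.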

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

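Of the tests in this part, those of GC content, of liver RNA in aged replicate 3 and of uterine tissue were fixed before their results were seen, and those of RNA quality, of liver RNA carried into the libraries, of a change with age, and all splits of the libraries were chosen after. In 132 groups over 22 quantities, 14 values of single libraries lay far from the rest of their group by Dixon's criterion, where chance gives about 6.6.

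The first pattern is the set of 67 genes called between TRi-1 and aged untreated ovaries. Across all tested genes the TRi-1 change correlated with GC content (Spearman rho = -0.244), but a GC and length bias as the whole cause is argued against, since after offsets for both the ratio of their median absolute log2 fold change to the original was 0.883 (1.21 to 1.07, quartiles of the ratio 0.836 to 0.979), and 31 of 67 stayed past the threshold. For liver RNA in aged replicate 3, the ratio without that library was 0.976 (quartiles 0.912 to 1.03), all 67 kept their sign and 0 were on the hepatocyte list. That list holds only part of the genes that liver may express. Fn1, which is not on it, had a smaller change without that library. Most of these changes thus kept their size without it. Genes that rest on 1 library are seldom called, though, so the ratio among called genes cannot exclude liver RNA. The calls ended without that library (smallest adjusted p = 0.058), where the median standard error was 0.242 against 0.224. Leaving out single libraries gave 0 to 164 genes, and only without aged replicate 2 did the count rise above 67. Whether the smaller group accounts for the lost calls cannot be told from this. An effect of TRi-1 and differences between mice in tissue content stay open, the latter since replicate 4 of the treated group stood apart in granulosa markers, and so does RNA quality, untested here, as the processed pseudogene share was 1.135 ± 0.182% with TRi-1 and 0.715 ± 0.229% without.

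The second pattern is young replicate 3 and auranofin replicate 3 of experiment 2, low in steroid and adipocyte genes and high in oviduct and uterine markers (6.86 and 6.08 log2 CPM). RNA quality cannot be told apart from other causes: the share of processed pseudogene counts, the 1 sign of it tested, lay outside the range of the other libraries (0.537 to 1.72%) in 0 of these 2. Uterine or oviduct tissue may be a source, but the smaller difference of the uterine patterning list from the highest other library was -0.946, and it cannot be told apart either. In the young library the 12 genes had a median of 3.98 against 4.93 in the highest other, while in the auranofin library it was 4.09 against 3.45, with Hoxa11 at 77.1 CPM against 1.73 to 17.2. High levels in other young libraries keep this open, and no biological explanation was tested.

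The third pattern is liver transcripts in experiment 1, where 10 libraries had a hepatocyte list median above 1. Liver RNA carried into the libraries in varying amount cannot be told apart from shared regulation: over the 13 libraries, centred by group, levels of the 29 tested hepatocyte genes correlated with a median Spearman rho of 0.736 (quartiles 0.577 to 0.857), but 2 of 32 other lists were as high (median of the lists 0.225). A change with age cannot be told apart either: the list mean was 2.21 ± 2.25 in aged and 2.54 ± 0.73 in young ovaries (exact permutation p = 0.770, 2-sided; 0.452 in experiment 2), a spread too wide to decide, while the median change of the 29 tested genes was 1.22. In experiment 2 the list mean was -0.0048 ± 0.46 in young and 0.18 ± 0.30 in aged ovaries. Young libraries ran from 1.865 to 3.63 in experiment 1 and reached at most 0.81 in experiment 2. A difference between young and aged mice alone thus does not account for the level in experiment 1. Aged untreated libraries of both experiments overlapped (-0.26 to 5.09 against -0.19 to 0.62). The point at which liver RNA would have entered is not recorded.

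Hmox1 (4.81), Srxn1 (2.62) and Hspb8 (2.13) differed between the treatment effects by the test of the difference, and the experiment differs along with the compound, with dose and timing not given.

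Single libraries far from their group are given as the gap to the nearest library over the group's range. Haemoglobin took 4.50% of counts in TRi-1 replicate 2 against 10.8 to 11.9% in the others (0.844), and 5.19% in young replicate 2 of experiment 2 against 0.289 to 1.46% (0.762). Processed pseudogenes took 1.02% in young replicate 3 of experiment 1 against 1.69 to 1.94% (0.724). Txnrd1 stood at 104.9 CPM in young replicate 3 of experiment 2 against 22.4 to 41.4 (0.769), and Cxcl10 at 5.36 in young replicate 4 against 0.626 to 1.93 (0.725). Srxn1 stood at 49.5 CPM in aged replicate 5 of experiment 2 against 66.8 to 69.8 (0.853), and Gclm at 31.3 in aged replicate 3 against 23.8 to 25.6 (0.762). In mean log2 CPM, young replicate 3 of experiment 2 stood at -1.72 for oocyte genes against 1.47 to 2.48 (0.760), at 1.2 for steroid genes against 5.14 to 5.73 (0.871), at 1.79 for granulosa markers against 3.41 to 4.05 (0.715) and at 2.55 for adipocyte markers against 5.06 to 5.93 (0.743). Auranofin replicate 3 stood at 3.83 for adipocyte markers against 6.59 to 6.93 (0.890), TRi-1 replicate 4 at 3.92 for granulosa markers against 2.29 to 2.48 (0.883), and young replicate 1 of experiment 2 at 0.81 for hepatocyte markers against -0.28 to -0.15 (0.880).

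Other splits of the libraries were run for each count of called genes. Only the real split gave as many genes for age in experiment 1 (1 of 100, 5590 against at most 2435) and in experiment 2 (1 of 100, 1705 against 25). The same held for age over both (1 of 100, 6173 against 544), and these shares argue against chance. For TRi-1 the real split was also the only one (1 of 35, 67 against 2). Yet 0 of those 67 genes passed without aged replicate 3, TRi-1 replicate 1 or TRi-1 replicate 4, so chance differences between mice are not excluded. For auranofin the share was low (2 of 100). However, 1 other split, of aged replicates 1 and 3 with auranofin replicates 1 and 2 against the rest, gave the same count (3 against 3). Unlike the TRi-1 calls, all 3 auranofin calls stayed with each library left out in turn. That is no test of chance, and with this tie the splits do not exclude chance for auranofin either. Chance is also not excluded for the difference of the treatment effects (5 of 100 splits, 3 against at most 14). For the 2 difference tests libraries were exchanged between the experiments within a condition. Differences between the experiments thus enter these splits, which cannot decide about chance. For the difference of the age effects the real count was 0, which each of the 100 splits reaches (100 of 100; at most 104), so the splits say nothing about chance there. The split of experiment 1 with 2435 genes set young replicates 1, 2, 4 and 5 against the rest, so it parts mostly young from aged. The 104 genes of a split for the difference of the age effects came from libraries so exchanged between experiments. Their source was not examined.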

How the results depend on the processing

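Of the results on single genes and lists, 7436 values under an alternative kept their direction and side of the threshold, 490 no longer passed, 82 newly passed, 23 moved and 0 reversed. Of the leading counts and set tests 290 stayed the same, 56 moved, 3 passed anew and 3 no longer passed. Where a result moved, the cause was not tested. Tests chosen after the data were seen are those on haemoglobin, GC content, groups of libraries and list tests with a library left out. Age counts stayed within 1.5 times in experiment 1 (4794 to 5451 with a library left out) and over both (5721 to 6374), as did those of experiment 2 with a library left out (1171 to 1812) but not with voom (2642); the lower genes alone went down to 462. RLE size factors moved the median of all genes by less than 0.1.

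For TRi-1 (67 genes) the counts were 167 without a filter, 172 at 5 CPM or more, 580 with DESeq2, 0 with only the groups compared, 2 with all 27 libraries, 36 with GC offsets, 0 without young replicate 5, aged replicate 3 and TRi-1 replicate 1, and 0 to 164 with a library left out. For auranofin (3) they were 67 with DESeq2, 33 with voom, 10 with all 27 libraries and 8 without young replicates 2 and 3 and auranofin replicates 3 and 4. The difference of the age effects (0) gave 6 at 5 CPM or more, 179 with DESeq2, 33 with voom, 1 without haemoglobin genes, 1 with GC offsets, 1 without young and auranofin replicates 3, and 0 to 19 with a library left out. The difference of the treatment effects (3) gave 5 at 5 CPM or more, 97 with DESeq2, 30 with voom, 15 with GC offsets, 5 without young and auranofin replicates 3, and 2 to 10 with a library left out.

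With an estimated correlation 0 lists passed for age in experiment 1, 3 in experiment 2, 0 for TRi-1 and 1 for auranofin. With fry 0 passed for TRi-1 and 1 for auranofin, while for age each list that camera called passed fry too. Further age lists passed fry only. In experiment 1 these included cell cycle arrest and senescence genes (fry adjusted p = 0.0013), circadian clock genes (0.018) and extracellular matrix genes (0.041). NRF2 target genes did so in experiment 2 (0.0078). Oocyte genes gave fry adjusted p = 6.9e-08 in experiment 1 and 0.017 in experiment 2, and B cell and plasma cell markers 3.4e-06 and 1.1e-04. Granulosa markers passed fry in experiment 1 (0.0031) but not in experiment 2 (0.41). With a library left out 1 to 11 lists passed for TRi-1. Genes higher with age gave p = 0.173 under TRi-1 with an estimated correlation and 0.104 with fry. Genes lower with age gave p = 0.142 under TRi-1 with an estimated correlation and 0.044 with fry. Under auranofin the higher set gave 0.0011 with its top 200 genes, 0.099 without young and auranofin replicates 3, and 2.0e-04 to 0.804 with a library left out. The lower set gave 0.990 with fry, 0.426 without those libraries and 0.0207 to 0.803 with a library left out.

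The labels do not say whether replicate numbers pair the libraries. Correlations between same-numbered libraries ran from -0.20 to 0.44 and not every library correlated best with its own number, so pairing is neither shown nor excluded. With the number as a block the counts were 4127 and 1487 for age in experiments 1 and 2, 1 for TRi-1, 11 for auranofin and 1 for the difference of the treatments, where Srxn1 (adjusted p = 0.17) and Hspb8 (0.067) lost their calls. Depth limits what low-count genes can show, Il6 among them, and with 200 genes changed the share of simulated changes recovered was low under 4-fold.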

Other observations

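In this part the test of the NRF2 genes between the treatments was chosen after the result was seen, and all values were read after the comparisons. In experiment 1 the actin-binding Tagln -1.52 ± 0.39 and the mesothelial marker Lrrn4 -1.51 ± 0.41 fell with age, while muscle markers as a list did not pass (camera adjusted p = 0.66). The endoplasmic reticulum foldase Pdia4 -3.30 ± 0.47 and the mitochondrial chaperonin Hspe1 -1.08 ± 0.19 also fell there, while in experiment 2 the small heat shock gene Hspb1 1.06 ± 0.26 rose. The clock genes Nr1d2 1.04 ± 0.21 and Tef 0.84 ± 0.23 rose in experiment 1 and had adjusted p of 0.0013 and 0.0098.

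Both compounds inhibit thioredoxin reductase, so whether their effects on NRF2 target genes differ was tested as a hypothesis. The median difference of the effects over the 28 genes was 0.79 in favour of auranofin, with 24 positive, and camera gave p = 6.7e-09, or 0.00199 with an estimated correlation. Of these genes 2 passed over all genes and 7 adjusted over the list alone. The difference between auranofin and TRi-1 cannot be parted from that between the experiments, and the test followed the separate results for this list.

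In principal components of the 1000 most variable genes, the first component held 60.4% of the variance in experiment 1. In experiment 2 the first held 35.9% and the second 20.2%, and on the second young replicate 3 stood at -76.9 and auranofin replicate 3 at -56.2.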
